A study of Homo sapiens with 14 samples.

How the data were processed

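OCI-AML2 cells with intact RUNX1 or with R174* on 1 allele were sequenced as total RNA or as RNA pulled down by RiboLace. The deposited values are raw read counts per gene, in 1 table of 14 libraries keyed by versioned Ensembl gene IDs. Per the submitters' processing notes, STAR 2.6.0b, DESeq2 and the GRCh38 genome were used, with no role or order given for any of them. Per the labels' protocols, total RNA was treated with DNase and made into Illumina libraries, and cells were treated with DMSO or 100 nM HHT for 8 h. The counting program, annotation release, strandedness, removal of ribosomal RNA and making of the RiboLace libraries are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart.

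The table held 58037 gene IDs without repeats, of which 57433 matched GENCODE release 29 by ID (53647 with the same version) and took symbol, type and coordinates from it; 604 did not match and kept their IDs. All 14 columns were matched to labels and none was left out. Values were whole numbers, and library totals were 19250789 to 21925693 counts for total RNA and 465052 to 2034796 for RiboLace. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 3.14 to 12.5 and r of log CPM across genes of 0.9251 to 0.9978, so replicate spread and not counting error sets the precision of well-counted genes.

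Tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling, the quasi-likelihood F-test and Benjamini-Hochberg adjustment, and called genes at an adjusted p under 0.05. Each of 7 comparisons had its own fit. HHT against control used the 8 treated and control mutant libraries with line as a covariate, and the difference in HHT response between lines G7 and F3 was the interaction in those libraries. Mutant against wild type in total RNA used 6 libraries with F3 and G7 as 1 group, so that their difference counts as error. That fit treats libraries of the same line as independent, and wild type is the parent line alone. Its p-values therefore do not measure the spread between lines. RiboLace libraries were compared in a fit of their own 4. RiboLace against total RNA, in wild type and in mutant F3, and translational efficiency came from 1 fit of 8 libraries with total RNA of line F3 alone as the mutant match. That fit gives both assays the same spread per gene, so its standard errors and p-values can be too small where RiboLace varies more. CPM in the text are scaled by TMM within each assay. Fold changes are log2. Their standard error (SE) is approximate, taken as the absolute log2 fold change divided by the square root of the F statistic.

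Before the data were examined, the comparisons, tests, alternatives, lists and rule for named genes were fixed. Named were the 8 largest rises and 8 largest falls per comparison among protein-coding genes past the threshold, with no overlap between groups and a mean CPM of at least 5, then RUNX1, MYC, MYB, MCL1, BCL2, BCL2L1, SPI1, CEBPA, CDK6 and LMO2, and up to 3 members of each described list with the smallest adjusted p, or the highest CPM where none passed. Genes with 0 reads in a group were given a bound at 3 reads over the group, and genes with 1 to 3 reads a ratio with its exact 95% interval. For translational efficiency, no value is given for genes with 1 to 3 reads in a group.

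The 32 lists held 1261 members from general knowledge. They covered the RUNX family and CBFB, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, the BCL2 family, haematopoietic transcription factors, genes regulated by RUNX1 or MYC, immediate early, inflammatory, interferon and MHC class II genes, the integrated stress, unfolded protein and heat shock responses, p53 targets, replication, mitosis, core histones, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrial transcripts, the proteasome, substrates of nonsense-mediated decay, nuclear noncoding RNAs, and markers of myeloid, erythroid, megakaryocyte, lymphoid and adherent cells. Lists were tested with camera of limma 3.58.1 on log CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation no list passed in any of the 7 comparisons.

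Other settings tried were RLE size factors, library totals alone, no filter, DESeq2 1.42.0, limma-voom, removal of mitochondrial, ribosomal protein and nuclear noncoding genes, each library left out in turn, other treatments of the lines, replicate numbers as a block and a 2-fold minimum. Protein-coding genes alone and removal of each library's trend with exon length were added after the data had been seen. The replicate numbers of the titles fall on the same lines in HHT and control libraries, and deviations of same-numbered libraries from their group means had r of 0.438 to 0.517; within lines the correlations were 0.0754 in F3 and 0.228 in G7. Much of the pairing of HHT and control lies in the line, which the fits hold as a term, and a further link between same-numbered libraries within lines is neither shown nor excluded.

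The fits were tested on simulated counts with 200 changed genes. Of genes changed 1.5-, 2- and 4-fold, 82.1%, 89.6% and 100% were recovered in a design as for HHT (13621 genes run), 32.8%, 74.6% and 98.5% as for mutant total RNA (13949 genes), 4.48%, 11.9% and 81.8% as for mutant RiboLace (9805 genes), 47.8%, 83.6% and 97.0% as for the line difference (14435 genes) and 0%, 22.4% and 56.1% as for translational efficiency (15338 genes). For RiboLace against total RNA (15338 genes) they were 11.9%, 49.3% and 71.2% in wild type and 16.4%, 46.3% and 69.7% in mutant F3. In the same order of designs, unchanged genes made up 5.73%, 8.05%, 0%, 5.59%, 3.7%, 4.35% and 5.38% of the calls. With only 200 genes changed, the runs do not test scaling or recovery where most genes move, as with HHT. Counts were drawn with the spread that each fit had estimated, the same for total RNA and RiboLace, and with libraries of a line independent. The runs therefore do not test these assumptions, and the shares of unchanged genes hold only if they are met.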

Results

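Gene-level read counts were measured in 14 libraries of OCI-AML2, a human acute myeloid leukaemia cell line in which RUNX1 was either intact on both alleles (wild type) or carried the R174* stop codon on 1 allele (mutant). RUNX1 encodes a DNA-binding transcription factor of blood cell development. Total RNA was sequenced in 2 wild-type libraries, 4 mutant control libraries and 4 mutant libraries treated with 100 nM HHT for 8 h. HHT is homoharringtonine, an inhibitor of translation elongation. RiboLace, a pull-down of RNA on active ribosomes by a puromycin-like probe, gave 2 wild-type and 2 mutant libraries. The mutant total RNA came from 2 lines, F3 and G7, with 2 libraries per line and treatment. Both mutant RiboLace libraries came from line F3. The wild-type total RNA libraries have the treatment label None and the mutant ones Control for 8 h. Another label gives 0 h for both and 8 h for the HHT libraries. The labels thus do not let genotype and control treatment be separated in total RNA. If the controls were taken at 0 h, HHT cannot be separated from time in culture either. The labels do not say whether replicates are separate cultures, so every p-value measures only the spread between these libraries.

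Depth differed strongly between the assays. Total RNA libraries held 19296906 and 21138358 counts in wild type, 19250789 to 21334260 in the 4 mutant controls and 20142280 to 21925693 after HHT. RiboLace libraries held 2034796 and 1054581 counts in wild type and 1192811 and 465052 in the mutant. Genes with at least 10 reads numbered 13290 to 13703 per total RNA library and 10854, 9536, 9837 and 7208 in the same RiboLace order. Protein-coding genes took 97.8% to 98.3% of total RNA counts and 74.5% to 77.9% of RiboLace counts. MIR6087, annotated as a microRNA precursor, was the most counted RiboLace gene, with 11.4% and 7.84% of wild-type and 9.0% and 4.64% of mutant counts. In total RNA the most counted gene was ACTB, cytoskeletal actin, in the wild-type and control libraries (1.47% to 1.68%) and EEF1A1, a translation elongation factor, after HHT (0.588% to 0.724%).

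**Figure D1:**
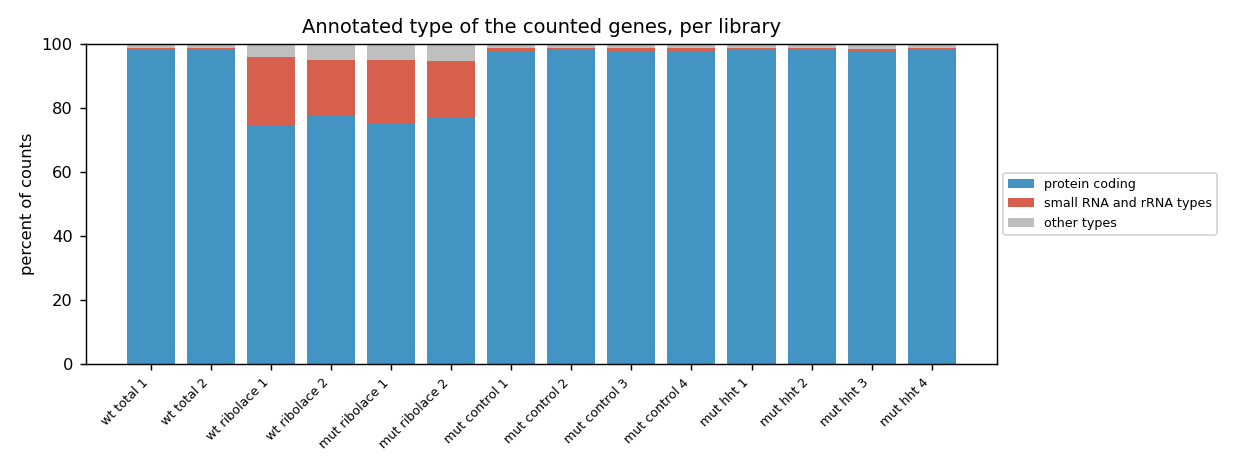
Percent of counts (vertical axis) in protein-coding genes, in small RNA and ribosomal RNA types and in other types, for each of the 14 libraries (horizontal axis). The small RNA share was 17% to 21.4% in the 4 RiboLace libraries and at most 0.898% in the 10 total RNA libraries.

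RUNX1 (ENSG00000159216.18, chromosome 21, 34787801 to 36004667 on GRCh38) was detected in every library. It stood at 142 and 132 CPM (counts scaled to library size) in wild-type total RNA, 80.0 and 84.3 in F3 controls and 134 and 117 in G7 controls. After HHT it stood at 141 and 143 CPM in F3 and 167 and 172 in G7. In RiboLace it stood at 141 and 164 in wild type and 140 and 139 in mutant F3. The mutant controls together held 104 ± 25.9 CPM (SD, n = 4) against 137 ± 7.05 in wild type (SD, n = 2), a log2 fold change of -0.41 ± 0.19 (SE) that did not pass the test (edgeR adjusted p = 0.256). It passed with line means (-0.44, adjusted p = 0.00253) and without a filter on low counts (adjusted p = 0.0207). By line, RUNX1 was lower in F3 than in wild type (log2 fold change -0.75 ± 0.11, adjusted p = 0.00015) and stood at -0.14 ± 0.11 in G7 (adjusted p = 0.431). G7 exceeded F3 by 0.61 ± 0.11 (adjusted p = 0.000942). A stop codon need not lower the RNA and the counts do not separate the alleles, so they do not check the genotype labels.

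**Figure D2:**
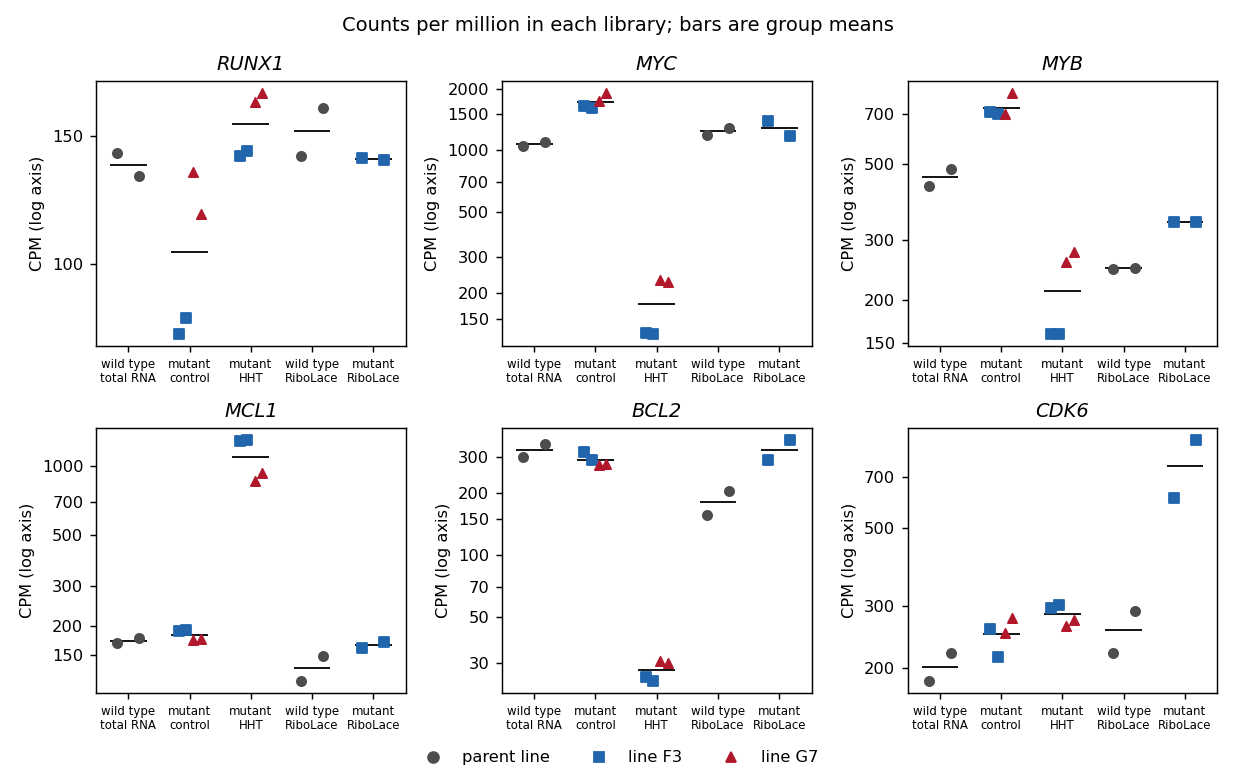
CPM on a log axis of RUNX1, MYC, MYB, MCL1, BCL2 and CDK6 in each library (points, shaped by line) with group means (bars), for the 5 groups. BCL2 went from 289 CPM in mutant controls to 27.6 after HHT and MCL1 from 184 to 1100, while RUNX1 overlapped between wild-type and mutant total RNA.

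The first comparison set 4 mutant control libraries against 2 wild-type libraries of total RNA. The test counts the mutant libraries as independent, although they come from lines F3 and G7. ELANE, the granule protease neutrophil elastase, was at 400 ± 153 CPM in the mutant and 34.3 ± 3.97 in wild type, a log2 fold change of 3.54 ± 0.36 (SE, adjusted p = 0.00148). PRTN3, proteinase 3, rose by 2.02 ± 0.13 (adjusted p = 0.000137), EPX, eosinophil peroxidase, by 4.28 ± 0.75 (adjusted p = 0.0152) and BPI, a bactericidal granule protein, by 4.27 ± 1.00 (adjusted p = 0.0453). EPHB2, an ephrin receptor, rose by 4.25, KLHDC7B by 4.02, HHLA2, a B7 family ligand, by 3.74, MGLL, monoacylglycerol lipase, by 3.66 and IFI27, an interferon-induced gene, by 3.49.

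The largest falls were in C12orf75 (log2 fold change -2.57 ± 0.11, adjusted p = 1.6e-05), PLEKHO1 (-2.30), MCEMP1 (-2.27), CD1D, a lipid antigen presenter (-2.26), RNASE6 (-2.09), LST1 (-1.73), FGR, a Src family kinase (-1.69), and S100A9, a calprotectin subunit of monocytes and neutrophils (-1.68). MYC, a transcription factor of growth, rose by 0.68 ± 0.10 (adjusted p = 0.00868), and MYB, a factor of immature blood cells, by 0.66 ± 0.11 (adjusted p = 0.0104). The apoptosis inhibitors MCL1 at 0.08, BCL2 at -0.17 and BCL2L1 at -0.18 did not pass the test, nor did SPI1 at -0.20, CEBPA at -0.50, CDK6 at 0.31 and LMO2 at 0.16.

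Among the gene lists, interferon-stimulated genes and DNA replication genes moved furthest by rank of the set test. Of 42 interferon genes 24 rose and none fell (33 rose when adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 7.61e-20, adjusted p = 0.528 with an estimated correlation). Examples were OAS2, an RNA sensor (1.53 ± 0.18), BST2, tetherin (1.21 ± 0.10), and IFIH1, the sensor MDA5 (1.01 ± 0.11). Of 56 replication genes 21 fell and none rose (48 fell when adjusted over the list alone), with a median of -0.47 (adjusted p = 8.05e-22, adjusted p = 0.259 with an estimated correlation). GINS2, a subunit of the replicative helicase, stood at -0.99 ± 0.09, RRM2, a subunit of ribonucleotide reductase, at -0.69 ± 0.11 and SLBP, the histone stem-loop binding protein, at -0.54 ± 0.09. MHC class II genes had a median of 1.27, with 2 of 10 rising (6 when adjusted over the list alone; adjusted p = 0.000189, and adjusted p = 0.626 with an estimated correlation). HLA-DRA rose by 2.51 ± 0.33.

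Other lists passed the set test in the mutant, each with adjusted p = 0.626 with an estimated correlation. Transcripts of the mitochondrial genome had a median of 0.66, with 4 of 13 rising (8 when adjusted over the list alone; adjusted p = 1.7e-05), among them MT-ND1 by 0.91 ± 0.18. Nuclear genes of oxidative phosphorylation had a median of -0.25 and 5 of 69 fell (22 when adjusted over the list alone; adjusted p = 7.4e-11). COX7B stood at -0.57. Proteasome genes had a median of -0.25 and 2 of 36 fell (12 when adjusted over the list alone; adjusted p = 3.18e-07). Mitotic genes had a median of -0.20 and 1 of 59 fell, AURKB (13 when adjusted over the list alone; adjusted p = 4.51e-07). Mitochondrial ribosomal proteins had a median of -0.18 with 4 of 77 falling (4 when adjusted over the list alone; adjusted p = 8.2e-08). Cholesterol synthesis genes had a median of -0.23 with 2 of 29 falling (3 when adjusted over the list alone; adjusted p = 0.00035), a call lost with F3 alone (-0.17, adjusted p = 0.0848). Genes of the integrated stress response, which ATF4 drives, had a median of 0.23 with 2 of 44 rising (3 when adjusted over the list alone; adjusted p = 0.000189). The latter shift was carried by F3, with a median of 0.06 and no call with G7 alone (adjusted p = 0.18).

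Genes known to respond to RUNX1 had a median of 0.24, with 7 of 28 rising and 1 falling (9 and 3 when adjusted over the list alone; adjusted p = 0.00759, and adjusted p = 0.585 with an estimated correlation), a call lost without wild-type replicate 2 (adjusted p = 0.0882). The 2 with the smallest p beside ELANE were PRTN3 and MYL9, a myosin light chain (1.42 ± 0.13). Myeloid markers went both ways, 7 of 33 up and 4 down (9 and 8 when adjusted over the list alone), with a median of -0.20 and a mean of 0.10 (adjusted p = 0.95). Among haematopoietic transcription factors 3 of 35 rose (3, with 1 falling, when adjusted over the list alone; adjusted p = 0.241). GATA2 rose by 2.6 ± 0.43. Cytosolic ribosomal protein genes had a median of -0.07 with 0 of 80 called by edgeR and 0 when adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.902 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.73) or mutant replicate 3 (0.57) or 4 (0.0692), and a median that turned to 0.02 with F3 alone.

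In all, 636 of 13949 genes passed (347 up, 289 down), 222 of them with at least a 2-fold change. The count depended on how the lines and low counts were treated, with 2846 for line means, 3080 for F3 alone, 2059 for G7 alone, 1655 without a filter and 1084 in DESeq2. It also rested on both wild-type libraries. Only 43 genes passed without wild-type replicate 1 and 63 without replicate 2. EPX, BPI, EPHB2, KLHDC7B, HHLA2, MGLL, IFI27, RNASE6, S100A9, MYC and MYB lost their calls without either of them, at adjusted p = 0.0557 to 0.338. BPI also lost it without mutant replicate 4 (adjusted p = 0.0618) and S100A9 without replicate 2 (adjusted p = 0.0594). ELANE, C12orf75, PLEKHO1, MCEMP1, CD1D, LST1 and FGR kept it without any single library.

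The second comparison asked what HHT changed in mutant cells, with 4 treated and 4 control libraries and line as a covariate. The controls are labelled both 8 h and 0 h, so a difference in time in culture may be part of these changes. Most expressed genes moved. Of 13621 tested, 10793 passed, 5438 up and 5355 down, and 4338 changed at least 2-fold. The steepest rises were in genes barely expressed in controls, such as CLDN1, a tight junction protein (log2 fold change 7.37 ± 0.24, adjusted p = 5.94e-12), the chemokines CCL3 (6.88 ± 0.19), CCL4 (6.99) and CCL4L2 (6.79), TMEM217 (6.68), DUSP8, a phosphatase of stress kinases (6.14 ± 0.13), PHLDA1 (5.68) and TNFRSF12A (5.67). CCL3 and CCL4 may share reads with the copies CCL3L1 and CCL4L2, which could not be checked, so the split between copies is uncertain. The steepest falls were in TBC1D30, a Rab regulator (-8.08 ± 0.11, adjusted p = 2.83e-15), NUPR1 (-6.21), AC119396.1 (-5.98), CIITA, the activator of MHC class II genes (-5.79 ± 0.22), SELPLG, the P-selectin ligand (-5.45 ± 0.07), SORL1 (-5.17), PRTN3 (-5.13 ± 0.09) and DACT3 (-5.06).

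BCL2 and MCL1 moved in opposite directions. BCL2 fell from 289 ± 20.3 to 27.6 ± 3.05 CPM (log2 fold change -3.39 ± 0.09, adjusted p = 1.35e-12). MCL1 rose from 184 ± 9.42 to 1100 ± 229 CPM (2.55 ± 0.08, adjusted p = 3.53e-12). PMAIP1, the MCL1 antagonist NOXA, rose by 2.66 ± 0.08 and BCL2L1 by 0.50. MYC fell from 1720 ± 128 to 178 ± 58.9 CPM (-3.33 ± 0.12, adjusted p = 1.83e-11), MYB stood at -1.83 ± 0.12 and CEBPA at -1.25. RUNX1 rose by 0.61 ± 0.07 (adjusted p = 3.98e-06) and SPI1, the myeloid factor PU.1, by 0.58. CDK6 at 0.18 (adjusted p = 0.0531) and LMO2 at -0.14 (adjusted p = 0.0671) did not pass, though CDK6 passed without control replicate 4 (adjusted p = 0.026) or HHT replicate 3 (0.0269) and LMO2 without control replicate 1 (0.0265) or 4 (0.0208).

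Immediate early genes rose most as a group, 50 of 58 up and 2 down (50 and 2 when adjusted over the list alone), with a median of 2.47 (camera adjusted p = 1.79e-10, adjusted p = 0.165 with an estimated correlation). EGR1 rose by 5.59 ± 0.09 to 471 ± 24.8 CPM and KLF10 by 4.78 ± 0.08. Core histone genes had a median of 1.85 with 36 of 36 up (36 when adjusted over the list alone; adjusted p = 8.06e-09, and adjusted p = 0.211 with an estimated correlation). HIST1H4H rose by 3.36 ± 0.14. Core histone genes together held only 84.9 to 96.8 CPM in controls and 347 to 401 after HHT, against 6540 to 19200 in untreated RiboLace. The rise thus concerns the small part of their RNA that total RNA captured. At least 10 reads were found for 29 to 32 members per control library and 38 to 41 after HHT. Members that passed the filter through the HHT libraries alone would favour rises. Inflammatory genes had a median of 1.49 with 23 of 31 up and 4 down (23 and 4 when adjusted over the list alone; adjusted p = 0.000924, and adjusted p = 0.165 with an estimated correlation). Interferon genes had a median of 1.13 with 34 of 43 up and 7 down (34 and 7 when adjusted over the list alone; adjusted p = 3.89e-05, and adjusted p = 0.407 with an estimated correlation). Targets of p53 had a median of 0.57 with 22 of 40 up and 7 down (22 and 7 when adjusted over the list alone; adjusted p = 0.00746, and adjusted p = 0.261 with an estimated correlation), among them BTG2 (5.36 ± 0.20) and CDKN1A, the inhibitor p21 (3.01 ± 0.09).

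Falls covered metabolism and protein handling. Glycolysis and hypoxia genes had a median of -1.90 with 33 of 34 down (33 when adjusted over the list alone; adjusted p = 5.54e-11, and adjusted p = 0.235 with an estimated correlation), such as SLC2A1, the glucose transporter GLUT1 (-3.75 ± 0.08). Cytosolic ribosomal protein genes had a median of -0.73 with 79 of 80 down and 1 up (79 and 1 when adjusted over the list alone; adjusted p = 3.25e-13, and adjusted p = 0.433 with an estimated correlation). RPL12 stood at -1.02 ± 0.06. Cholesterol synthesis genes had a median of -0.92 with 26 of 29 down and 2 up (26 and 2 when adjusted over the list alone; adjusted p = 8.25e-06, and adjusted p = 0.282 with an estimated correlation). INSIG1 stood at -3.50 ± 0.07. Integrated stress response genes had a median of -0.97 with 33 of 43 down and 8 up (33 and 8 when adjusted over the list alone; adjusted p = 5.62e-05, and adjusted p = 0.406 with an estimated correlation). PSAT1, of serine synthesis, fell by 3.84 ± 0.08. ATF3, a stress-induced factor also counted among transcripts subject to nonsense-mediated decay, rose by 3.30 ± 0.08. Unfolded protein response genes had a median of -0.92 with 19 of 26 down and 3 up (19 and 4 when adjusted over the list alone; adjusted p = 0.000317, and adjusted p = 0.165 with an estimated correlation). PDIA4 stood at -2.60 ± 0.07.

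Oxidative phosphorylation genes had a median of -0.29 with 47 of 68 down and 6 up (47 and 6 when adjusted over the list alone; adjusted p = 0.000603, and adjusted p = 0.656 with an estimated correlation). Mitochondrial genome transcripts had a median of -0.95 with 13 of 13 down (13 when adjusted over the list alone; adjusted p = 0.00194, and adjusted p = 0.522 with an estimated correlation). MHC class II genes had a median of -1.23 with 8 of 8 down (8 when adjusted over the list alone; adjusted p = 0.00533, and adjusted p = 0.302 with an estimated correlation), the invariant chain CD74 at -2.12 ± 0.10. Myeloid markers had a median of -0.68 with 20 of 32 down and 5 up (20 and 5 when adjusted over the list alone; adjusted p = 0.00807, and adjusted p = 0.165 with an estimated correlation). RUNX1-responsive genes had a median of -0.59 with 19 of 28 down and 6 up (19 and 7 when adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.261 with an estimated correlation). ELANE fell by 1.64 ± 0.06. Replication genes had a median of 0.36 with 34 of 56 up and 12 down (34 and 12 when adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.656 with an estimated correlation), a call lost with G7 alone (0.21, adjusted p = 0.069). Nonsense-mediated decay substrates had a median of 0.52 with 25 of 40 up and 11 down (25 and 11 when adjusted over the list alone; adjusted p = 0.0286, and adjusted p = 0.433 with an estimated correlation). The snoRNA host gene SNHG12 rose by 2.04 ± 0.06.

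**Figure D3:**
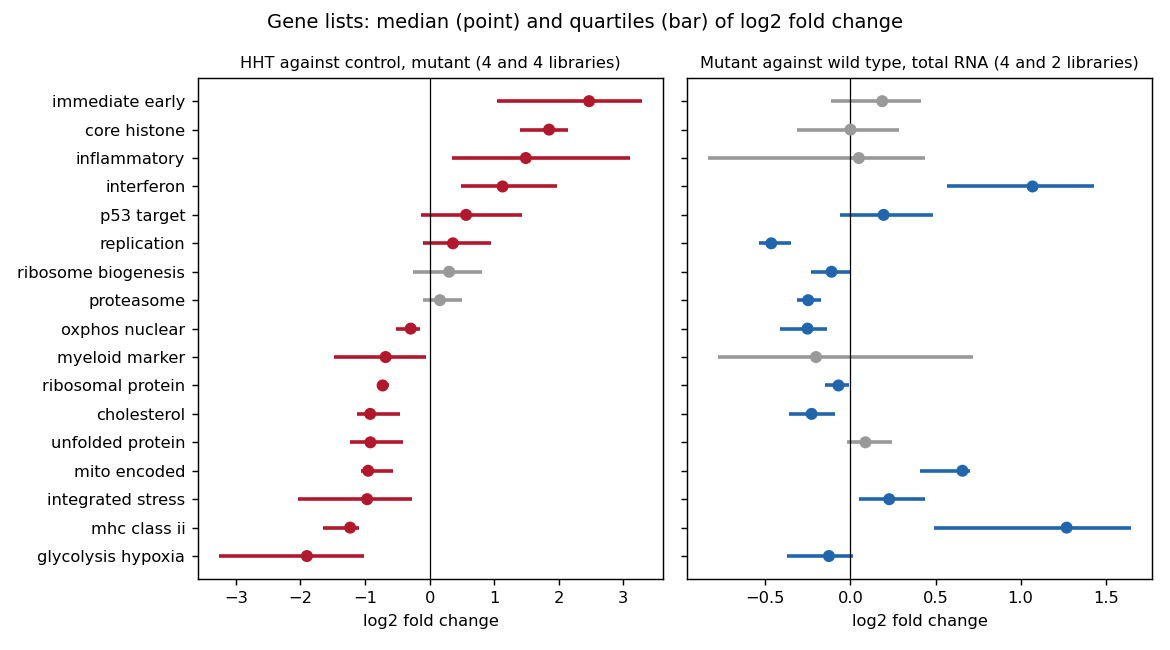
Median (points) and quartiles (bars) of log2 fold change of each gene list (horizontal axis, log2) for HHT against control in mutant cells (left, 4 and 4 libraries) and mutant against wild type (right, 4 and 2 libraries); grey lists did not pass camera with the preset correlation. Immediate early genes lie at 2.47 and glycolysis and hypoxia genes at -1.90 with HHT, and interferon genes at 1.07 and replication genes at -0.47 in the mutant.

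The HHT count was 4338 with a 2-fold minimum and lay between 9676 (G7 alone) and 11960 (no filter on low counts) in the other settings. The 24 named genes that passed kept their call and direction under all 19 alternatives. With library totals in place of TMM scaling the median of all genes moved to 0.23 and 6684 rises stood against 4115 falls, so directions of small changes are relative to the median gene.

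Lines F3 and G7 differed in how far HHT moved some genes. MYC changed by -2.96 in G7 and -3.68 in F3 (difference 0.71 ± 0.11, adjusted p = 0.00162). MYB changed by -1.47 and -2.15 (0.68 ± 0.11, adjusted p = 0.00293). BCL2 changed by -3.16 in G7 and -3.60 in F3 (0.44 ± 0.12, adjusted p = 0.0424), a call lost without any 1 of 5 libraries, control replicate 1 or an HHT replicate (adjusted p = 0.114 to 0.268). RIN3, a Rab5 regulator, changed by -3.22 in F3 and -1.09 in G7, and RGS16, a G protein regulator, by -0.60 in F3 and 0.84 in G7. SLC2A3, the glucose transporter GLUT3, stood at -1.39 in F3 and 0.08 in G7. MCL1 (-0.38, adjusted p = 0.0555) and RUNX1 (-0.33, adjusted p = 0.135) did not pass, RUNX1 doing so only without control replicate 4 (adjusted p = 0.0288) or with the replicate numbers as a block (adjusted p = 0.00532). MCL1 also passed with the block (adjusted p = 0.00106).

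In the difference between lines, 13 of 43 interferon genes were lower and 1 higher (19 and 1 when adjusted over the list alone), with a median of -0.21 (camera adjusted p = 3.09e-07, adjusted p = 0.571 with an estimated correlation). IFI6 stood at -0.94 ± 0.13. Replication genes had a median of -0.22 with 6 of 56 lower (15 when adjusted over the list alone; adjusted p = 3.49e-08, and adjusted p = 0.623 with an estimated correlation). Immediate early genes had a median of -0.21 with 12 of 59 lower and 4 higher (19 and 5 when adjusted over the list alone; adjusted p = 0.000661, and adjusted p = 0.623 with an estimated correlation). For 548 of 14435 genes the response differed (259 higher in G7, 289 lower), against 178 without control replicate 1, 1089 without control replicate 4, 823 without a filter on low counts and 2153 with the replicate numbers as a block. DNASE2 (1.33) lost its call without control replicate 1 (adjusted p = 0.0598) or HHT replicate 1 (0.0724) or 4 (0.0799), GPNMB (2.18) without HHT replicate 4 (0.101), and HSPG2 (1.59), FADD (-2.19) and C4orf48 (-2.04) without control replicate 1 (0.0503, 0.0725 and 0.0817). NDUFAF8 (-1.67) lost it without control replicate 1 (0.164), 2 (0.0803) or 3 (0.0509) or HHT replicate 3 (0.0517).

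RiboLace was next compared with total RNA within each genotype, which shows the RNAs over- or under-represented on the beads. Assay and preparation cannot be told apart. The fit gives both assays the same spread per gene, so its p-values can be too small if RiboLace varies more. Core histone genes, whose main RNAs end in a stem-loop instead of a poly(A) tail, were far higher in RiboLace, 42 of 43 up in wild type (43 when adjusted over the list alone) with a median log2 ratio of 8.58, or 8.53 with genes at 0 reads set to their bounds (camera adjusted p = 5.3e-27, adjusted p = 0.403 with an estimated correlation). In mutant F3 the median was 7.16, or 7.12 with bounds, and 42 of 43 were up (42 when adjusted over the list alone; adjusted p = 1.46e-22, and adjusted p = 0.525 with an estimated correlation). HIST1H4B had 1235 wild-type RiboLace reads and 3 total RNA reads, a ratio of 5390 (95% counting interval 1840 to 26200). Such intervals and the bounds below, which set a zero group to 3 reads over the group, cover counting error only. Histone genes may also share reads with near-identical copies, which could not be checked.

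Some genes without reads in total RNA had many in RiboLace. CXXC4, a Wnt regulator, had 7258 wild-type RiboLace reads and 0 in total RNA (at least 31700-fold higher), ZIC5, a neural transcription factor, 5018 and 0 (at least 21900-fold), MAF 3870 and 0 (at least 16900-fold), GSG1L 3468 and 0 (at least 15100-fold), FEZF2 3420 and 0 (at least 14900-fold), ELAVL2 2139 and 0 (at least 9330-fold), NKX2-8 1464 and 0 (at least 6390-fold) and RELN 1014 and 0 (at least 4420-fold). In mutant F3 the bounds were 34900-fold for CXXC4, 26400 for MAF, 12900 for GSG1L, 12500 for FEZF2, 7880 for ELAVL2, 5580 for HRK and 5530 for SLC6A2, and ZIC5 had a ratio of 81300 (14600 to 3210000). RUNX2 was 6.27 ± 0.27 higher on the log2 scale in wild-type RiboLace and 5.68 ± 0.26 in F3.

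Lower in RiboLace with few or no reads there were GOLGA8N (0 against 638 reads, at least 16.2-fold lower), HNRNPA1P48 (0 against 490, at least 12.5-fold lower) and FAM72A (1 against 730, a ratio of 55.8, 9.98 to 2210), all with near-identical copies. Measured falls were large in RPS28 (-7.68 ± 0.32), RPL7 (-6.37 ± 0.31), TBC1D30 (-5.89 ± 0.30), ADM, the peptide adrenomedullin (-5.89), and RPS3A (-5.50). In mutant F3, ADM had 0 against 9007 reads (at least 120-fold lower). SYT11 and S100A8 also had 0 reads there, with bounds of only 4.35- and 1.79-fold, and S100A8 lost its call without mutant RiboLace replicate 1 (adjusted p = 0.187). Measured falls in F3 were large in RPL7 (-7.55), TBC1D30 (-6.82), RPS28 (-6.48), BNIP3 (-5.42) and FCGR1A (-5.38).

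Cytosolic ribosomal protein genes had a median log2 ratio of -1.36 in wild type with 57 of 80 lower and 5 higher (60 and 5 when adjusted over the list alone; adjusted p = 3.04e-13, and adjusted p = 0.943 with an estimated correlation), and of -2.04 in F3 with 73 lower and 2 higher (73 and 2 when adjusted over the list alone; adjusted p = 9.04e-19, and adjusted p = 0.612 with an estimated correlation). Glycolysis and hypoxia genes had medians of -1.97, or -1.95 with bounds, and -2.11, or -2.04 with bounds, with 31 of 34 lower in both genotypes (32 when adjusted over the list alone; adjusted p = 2.68e-13 and 2.3e-12, adjusted p = 0.403 and 0.525 with an estimated correlation). Translation factors had medians of -0.50 and -0.90 with 25 and 29 of 48 lower and 3 and 2 higher (27 and 30, with the same rises, when adjusted over the list alone; adjusted p = 5.26e-06 and 2.34e-05, adjusted p = 0.403 and 0.525 with an estimated correlation). EEF1A1 stood at -4.96 ± 0.23 and -5.0 ± 0.23. RPS28, RPL7, RPS3A, EEF1A1 and NPM1 (-3.83 ± 0.21 in wild type) have processed pseudogenes that can take or discard their reads. Nuclear noncoding RNAs had a median of 2.97 in wild type with 8 of 14 higher and 2 lower (8 and 3 when adjusted over the list alone; adjusted p = 0.147) and 3.17 in F3 with 11 of 14 higher (11 when adjusted over the list alone; adjusted p = 0.00238, and adjusted p = 0.556 with an estimated correlation).

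Of 15338 genes, 7407 differed between the assays in wild type (4194 higher in RiboLace, 3213 lower) and 7548 in mutant F3 (4063 and 3485), the latter count being 4720 without mutant RiboLace replicate 1. The balance of directions in wild type depended on scaling, with 3691 higher and 4020 lower by library totals and 4469 and 2808 by RLE size factors. CDK6 was higher by 0.52 in wild type and 1.78 in F3, CEBPA by 1.25 and 1.27, MYB stood at -0.70 and -0.93, and RUNX1 stood at 0.34 (adjusted p = 0.091) and 0.90 (adjusted p = 0.000191). BCL2 (-0.66 in wild type) lost its call without wild-type total RNA replicate 2 (adjusted p = 0.101), CDK6 in wild type without total RNA replicate 1 (adjusted p = 0.192) or RiboLace replicate 2 (0.214), and SPI1 (-0.54 in F3) without any 1 of 5 libraries, both wild-type total RNA ones, both F3 controls and mutant RiboLace replicate 2 (adjusted p = 0.0761 to 0.313).

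Mutant and wild-type RiboLace libraries were then compared, 2 of line F3 against 2. CDK6, a cell cycle kinase, stood at 749 ± 198 CPM in the mutant and 256 ± 50.1 in wild type (SD, n = 2 each), a log2 fold change of 1.55 ± 0.30 (SE, adjusted p = 0.0012). ELANE rose by 2.52 ± 0.30 (adjusted p = 1.91e-06), GATA2, a stem cell transcription factor, by 2.09 ± 0.28, MGLL by 3.20 ± 0.52, SERPING1, the C1 inhibitor, by 3.57, KIF5C by 3.79, PTPRS by 2.96 and PPP1R1B by 2.88. INO80C, at 4.72 ± 0.72, rested on mutant replicate 2, without which it stood at 1.42 (adjusted p = 0.358). CD84 had 22 against 3 reads (ratio 13.7, 4.11 to 71.3) and ANKRD55 16 against 2 (14.9, 3.50 to 134).

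Among myeloid markers 7 of 25 fell in mutant RiboLace and 2 rose (11 and 3 when adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.0279, adjusted p = 0.718 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.126) or mutant replicate 1 (0.0632) or with the exon length trend removed (0.0942). S100A8, the partner of S100A9, had 0 reads against 38 (at least 6.8-fold lower), CSF1R, the macrophage growth factor receptor, 1 against 72 (ratio 38.6, 6.72 to 1550), ORM2 1 against 56 (30.1, 5.18 to 1210), RGS2 1 against 29 (15.6, 2.58 to 636), MCEMP1 2 against 56 (15, 3.97 to 127), CHI3L1 2 against 53 (14.2, 3.75 to 120) and LRP1 2 against 39 (10.5, 2.71 to 89.5). LYZ, lysozyme, fell by 2.69 ± 0.32, S100A9 stood at -2.51 ± 0.34 and FCER2, a low-affinity IgE receptor, at -3.04 ± 0.60. BCL2 rose by 0.84 ± 0.27 (adjusted p = 0.0401). RUNX1 at -0.13, MYC at 0.06, MYB at 0.45, MCL1 at 0.34, BCL2L1 at 0.60, SPI1 at -0.65, CEBPA at -0.28 and LMO2 at 0.39 did not pass.

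Core histone genes fell in mutant RiboLace, 36 of 40 (39 when adjusted over the list alone), with a median of -1.28 (camera adjusted p = 4.02e-21, adjusted p = 0.718 with an estimated correlation, as for every list that passed here). Oxidative phosphorylation genes had a median of -0.81 with 25 of 66 down (47 when adjusted over the list alone; adjusted p = 1.93e-13). COX7B stood at -1.52 ± 0.32. Cytosolic ribosomal protein genes had a median of -0.69 with 14 of 75 down (37 when adjusted over the list alone; adjusted p = 3.68e-11). RPL32 stood at -1.34 ± 0.30. Mitochondrial ribosomal protein genes had a median of -0.59 with 10 of 73 down (10 when adjusted over the list alone; adjusted p = 1.91e-08). Heat shock genes had a median of -0.72 with 10 of 23 down (14 when adjusted over the list alone; adjusted p = 1.89e-07), SERPINH1, a collagen chaperone, at -2.34 ± 0.30, and proteasome genes a median of -0.54 with 4 of 34 down (11 when adjusted over the list alone; adjusted p = 6.01e-05). Interferon genes had a median of 0.66 with 9 of 27 up and 1 down (11 and 1 when adjusted over the list alone; adjusted p = 6.01e-05). SAMD9L rose by 2.06 ± 0.41. Beside these groups, the nuclear RNAs MALAT1 (482 ± 92.0 to 4010 ± 1720 CPM, log2 fold change 3.05 ± 0.40, adjusted p = 5.64e-06) and NEAT1 (1.75 ± 0.32) rose in mutant RiboLace, with 4 of 10 nuclear noncoding RNAs up and 2 down (5 and 3 when adjusted over the list alone; adjusted p = 0.0992).

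In RiboLace 1154 of 9805 genes passed (606 up, 548 down), but 247 without mutant replicate 2, 280 without wild-type replicate 1, 581 without mutant replicate 1 and 1956 without wild-type replicate 2. DESeq2 called 328 and a fit of all 14 libraries gave 1963 (784 up, 1179 down). With the exon length trend removed 738 passed (346 up, 392 down), of which 561 were among the 1154. The balance of directions did not hold either, with 758 up and 485 down by library totals and 396 up and 626 down without a filter on low counts. SERPING1, ORM2 and MGLL kept their call without any single library. CDK6 lost it without mutant replicate 2 (adjusted p = 0.0706), and BCL2 without wild-type replicate 1 (adjusted p = 0.279) or mutant replicate 1 (0.113) or 2 (0.405). Of the genes with few reads, CSF1R, CHI3L1, ANKRD55, CD84, MCEMP1, LRP1 and PTPRS lost their call without wild-type replicate 1 (adjusted p = 0.0613 to 0.252), S100A8, FCER2, RGS2, MCEMP1, LRP1 and PPP1R1B without mutant replicate 1 (0.0601 to 0.136), and KIF5C, CD84, PTPRS, RGS2 and LRP1 without mutant replicate 2 (0.0842 to 0.195).

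Translational efficiency, the mutant change in RiboLace relative to that in F3 total RNA, was tested as the interaction of genotype and assay in 8 libraries. The fit gives both assays the same spread per gene. Its common coefficient of variation between replicates was 0.109, against 0.187 in the fit of RiboLace libraries alone. The SE and p-values below can therefore be too small. CDK6 stood at 1.26 ± 0.28 (adjusted p = 0.0297), PDE4D, a cyclic AMP phosphodiesterase, at 2.28 ± 0.38 (adjusted p = 0.00446) and TSPOAP1 at 1.90 ± 0.30 (adjusted p = 0.00413). KIF5C stood at 4.29, RPP14 at 2.33, TENT5C at 2.26, ZNF714 at 1.88, EPM2AIP1 at 1.85 and INO80C at 4.89, or 1.81 without mutant RiboLace replicate 2 (adjusted p = 0.191). Lower were FCER2 (-3.70 ± 0.54, adjusted p = 0.00148), DNASE2, a lysosomal nuclease (-3.83 ± 0.69) and GPNMB (-3.32). MILR1, CHI3L1, RGS2, ORM2 and CSF1R also passed as lower, with 1 to 3 reads each in mutant RiboLace, too few for a measured size. LYZ stood at -2.53 ± 0.35 (adjusted p = 0.000746). BCL2 at 0.87 (adjusted p = 0.0921), RUNX1 at 0.57 (adjusted p = 0.225), MYC at -0.60, MYB at -0.22, MCL1 at 0.14, BCL2L1 at 0.77, SPI1 at -0.54, CEBPA at 0.02 and LMO2 at 0.16 did not pass, BCL2 doing so only without wild-type RiboLace replicate 2 (1.03, adjusted p = 0.00315) or with 2 other settings.

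Translational efficiency of core histone genes had a median of -1.37 with 10 of 43 lower (28 when adjusted over the list alone; camera adjusted p = 2.38e-14, and adjusted p = 0.747 with an estimated correlation). HIST1H2AC stood at -2.31 ± 0.31. Core histone genes together had 72.1 to 96.8 CPM in wild-type and control total RNA and 6540 to 19200 CPM in RiboLace, so a lower amount of their RNA in the mutant would give the same value as lower ribosome loading. Cytosolic ribosomal protein genes had a median of -0.73 with 8 of 80 lower (42 when adjusted over the list alone; adjusted p = 1.73e-11, and adjusted p = 0.747 with an estimated correlation). RPL32 stood at -1.43 ± 0.30. Integrated stress response genes had a median of -0.68 with 7 of 43 lower (14 when adjusted over the list alone; adjusted p = 1.47e-08, and adjusted p = 0.747 with an estimated correlation), ASNS, asparagine synthetase, at -1.77 ± 0.29, and myeloid markers a median of -0.60 with 3 of 32 lower (12 when adjusted over the list alone; adjusted p = 7.62e-05, and adjusted p = 0.747 with an estimated correlation). Heat shock genes had a median of -0.43 with 4 of 25 lower (7 when adjusted over the list alone; adjusted p = 0.00011, and adjusted p = 0.747 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.63 with 0 of 69 called by edgeR (17 lower when adjusted over the list alone; camera adjusted p = 5.62e-06, and adjusted p = 0.835 with an estimated correlation). Beside these, MALAT1 stood at 2.89 ± 0.35 (adjusted p = 0.000364) and NEAT1 at 1.95 ± 0.34 (adjusted p = 0.00578). Both are nuclear noncoding RNAs, so their values cannot be read as more translation. What raised them was not tested and may also enter the values of other genes, CDK6 among them.

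**Figure D4:**
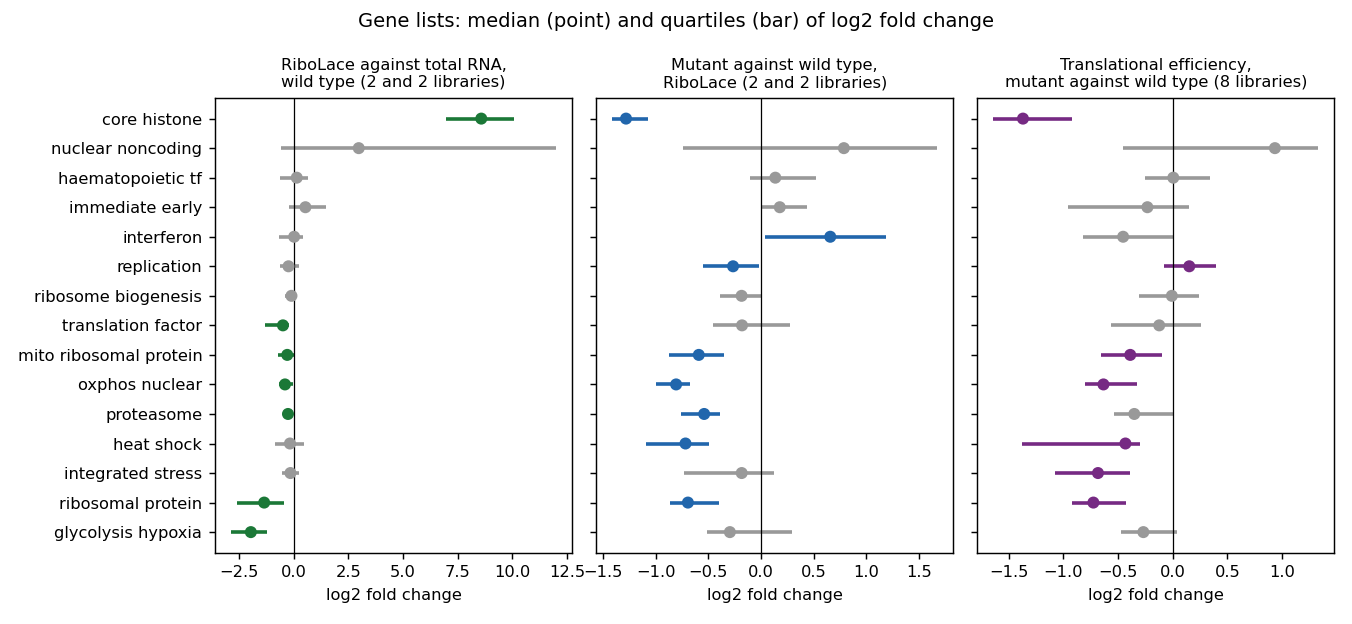
Median (points) and quartiles (bars) of log2 fold change of each gene list (horizontal axes, log2) for RiboLace against total RNA in wild type (left), mutant against wild type in RiboLace (middle) and translational efficiency (right), from 2 libraries per group; grey lists did not pass camera with the preset correlation. Core histone genes lie at 8.58, -1.28 and -1.37 and ribosomal protein genes at -1.36, -0.69 and -0.73.

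For translational efficiency 229 of 15338 genes passed (74 up, 155 down). Leaving out a library gave 24 and 25 without wild-type total RNA replicates 1 and 2 and 66 and 33 without F3 control replicates 1 and 2. It gave 140 and 29 without mutant RiboLace replicates 1 and 2, and 100 and 1498 without wild-type RiboLace replicates 1 and 2. Total RNA of F3 and G7 together left 11, limma-voom called 75 and library totals 151, while protein-coding genes alone gave 361, DESeq2 468 and no filter 527. The excess of falls shrank with library totals (72 up, 79 down), limma-voom (33 and 42) and DESeq2 (185 and 283). It stayed with protein-coding genes alone (110 and 251) and no filter (176 and 351). TSPOAP1 kept its call without any single library. PDE4D lost it without wild-type total RNA replicate 2 (adjusted p = 0.0961), FCER2 without mutant RiboLace replicate 1 (0.0694), and the other 13 of the 16 genes with the largest changes, like CDK6 (adjusted p = 0.0678 to 0.196), without at least 2 of the 8 libraries.

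Across genes, which are not independent replicates, mutant effects in total RNA and RiboLace, which share no library, had r = 0.481 and rho = 0.457 over 9000 genes. Of 478 genes called in total RNA, 410 (85.8%) had the same sign in RiboLace. Called in both were 70 genes up and 56 down, against 12.7 and 12.4 expected of independent lists, with 2 and 1 in opposite directions against 13.4 and 11.8. ELANE, MGLL, GATA2, MCEMP1 and S100A9 were among genes called the same way in both.

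HHT and mutant effects, which share the 4 mutant controls, had r = -0.105 and rho = -0.063 over 13363 genes with a covariance of -0.0552. Unchanged groups simulated 100 times against those controls gave a mean r of -0.413 and a mean covariance of -0.0204 (-0.0223 to -0.0184). Splitting the controls between the comparisons gave r from -0.104 to -0.0568 and covariances from -0.0531 to -0.0299. With the controls split, 106, 74, 111 and 85 genes higher in the mutant fell with HHT, against 58.3, 38.2, 63.4 and 45 expected of independent lists, and 31, 20, 36 and 24 rose, against 56.2, 36.9, 58.2 and 43.5. Of genes lower in the mutant, 33, 19, 33 and 27 fell, against 27.8, 17.2, 29.5 and 21.7. PRTN3 and ELANE, raised in the mutant with all 4 controls, fell with HHT.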

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

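The tests of RNA carry-over, of exon length, of the control treatment and of a change in 1 line were chosen only after the result was seen. So were the added settings used for replication genes. The tests of histone RNA ends, triplet repeats, the shallow library and chance were chosen before their own results were seen. All of these but the chance test concern patterns already seen in these data.

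RNAs abundant in RiboLace and nearly absent from total RNA formed the clearest technical pattern. Core histone RNAs lack poly(A) tails, while RNAs of the variant histone genes were taken to have them. The variant genes had a median log2 ratio of -0.42 in wild type and -0.40 in mutant F3, against 8.58 and 7.16 for core histones. They spread widely, from -3.87 (H3F3A) to 3.19 (H3F3C) in wild type and from -4.2 to 1.16 for the same genes in F3. The medians, but not every gene, go with poly(A) selection of the total RNA libraries alone, which no label states. At least 100 RiboLace reads and at most 3 in total RNA were found for 53 protein-coding genes, among them CXXC4, ZIC5 and MAF but also the histone genes HIST1H2AM and HIST1H2BH, and these took 0.966% to 1.76% of RiboLace counts. A run of 6 or more CGG-type triplets was found in 24.5% of them (13 of 53) against 1.26% of 5219 genes silent in both assays (66 genes, Fisher's exact test, two-sided, p = 3.61e-13). Reads shared with structured GC-rich RNA may account for such genes, but 40 of the 53 have no such run and no reads were available, so this and real transcripts without tails cannot be told apart.

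Ribosomal protein and core histone genes stood lower in RiboLace of mutant F3 relative to total RNA, with medians of -0.73 and -1.37. Removing each library's trend with exon length left -0.49 and -1.12, which argues against length as the whole cause, and leaving out the shallow mutant replicate 2 left -0.65 and -1.16. If the wild-type ratios came from the pull-down itself, more carried-over total RNA in the mutant would raise ribosomal protein genes (-1.36 in wild type). It would then lower core histone genes. The change of -0.73 in ribosomal protein genes goes the other way. Library making or reads lost to pseudogenes could also give the wild-type ratios, and carried-over RNA would share them. The test therefore cannot decide, and carry-over stays open for both lists. Lower ribosome loading in F3 remains as a hypothesis, as do a lower amount of core histone RNA, which total RNA hardly captured, and a difference in preparation between the genotypes that raised MALAT1 by 3.05 in mutant RiboLace, since no label gives a batch. With an estimated correlation neither list passed (adjusted p = 0.747 for both), and the series holds no RiboLace library of G7.

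Higher interferon genes and lower replication genes in mutant total RNA cannot be tied to genotype by the labels, because only the mutant libraries are labelled as control-treated. Another label gives 0 h for both genotypes, so whether their treatment differed is itself unsure. In RiboLace, where both genotypes have the treatment label None, interferon genes stood at 0.66 in the mutant with a gap of 0.41 between the groups' libraries, which argues against the control treatment as the whole cause for them. Replication genes stood at -0.27 with a gap of 0.20, and at -0.33 to -0.25 where leaving out a library or taking protein-coding genes alone ended the call (adjusted p = 0.0509 to 0.117), but at -0.09 with the exon length trend removed (adjusted p = 0.295), which leaves the control treatment open for them. A change of 1 line alone is unlikely for interferon genes, which had medians of 1.15 in F3 and 0.71 in G7 against wild type. An effect of RUNX1 R174* and a difference between the parent and both derived lines from cloning or culture stay open, untested.

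The HHT count was set against all 35 splits of the 8 libraries into 2 groups of 4. Without the line term the real split gave 9853 genes and the highest other, F3 against G7, gave 35. Only the real split reached its own count, 1 of 35, the smallest share that this test can give. All other splits put treated and control libraries in the same group, which favours low counts there. The test cannot tell whether the libraries are separate cultures.

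In groups of 4 libraries, 6 of 120 groups of values had a library far from the rest. Chance gives about 1 in 20 (5%) for values of a single population. Each group holds libraries of both F3 and G7, so that rate need not apply here. Mutant control replicate 4 was highest for TMEM217 at 0.212 CPM and for MYB at 808 CPM. Mutant control replicate 3 was highest for RAB5IF at 12.3 CPM and for TMEM160 at 25.9 CPM. Mutant control replicate 2 had the highest percent of protein-coding counts at 98.022. HHT replicate 4 was lowest for AC119396.1 at 0.0823 CPM.

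The HHT response differed between lines G7 and F3 for 548 genes by the interaction test. As G7 minus F3, the differences were 0.71 for MYC, 0.68 for MYB, 0.44 for BCL2, 2.18 for GPNMB, 2.14 for RIN3, 1.90 for IL1RN, 1.59 for HSPG2, 1.56 for VSIR, 1.47 for SLC2A3, 1.44 for RGS16 and 1.33 for DNASE2. They were -3.26 for RAB5IF, -2.47 for TMEM160, -2.19 for FADD, -2.17 for SYNPO2, -2.04 for C4orf48, -1.70 for FABP3, -1.68 for OTUD1 and -1.67 for NDUFAF8. The G7 controls were far apart for RAB5IF (12.3 and 4.61 CPM), TMEM160 (25.9 and 11.2), FADD (11.3 and 3.87) and C4orf48 (17.6 and 9.11), and the wild-type total RNA pair for RAB5IF (25.6 and 7.59), TMEM160 (47.5 and 17.8), NDUFAF8 (24.6 and 8.99) and C4orf48 (24.2 and 11.8). List medians of this difference were -0.21 for immediate early, 0.18 for integrated stress, -0.22 for replication, 0.0901 for cholesterol, 0.16 for glycolysis and hypoxia, -0.22 for oxidative phosphorylation, 0.39 for mitochondrial transcripts, -0.21 for interferon and 0.50 for MHC class II genes.

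The 2 mutant lines also differed without HHT, with 1743 genes called between G7 and F3 controls. The mutant effect in G7 exceeded that in F3 by 1.80 for EPX, 2.89 for BPI, 1.13 for EPHB2, 1.09 for HHLA2, 1.21 for MGLL, 0.98 for ELANE, 1.44 for S100A9 and 0.61 for RUNX1. It was lower in G7, with differences of -1.85 for KLHDC7B, -1.57 for IFI27, -0.72 for PLEKHO1, -1.18 for RNASE6 and -0.45 for LST1. List medians differed by -0.19 for ribosomal proteins, 0.17 for ribosome biogenesis, 0.15 for MYC-regulated genes, -0.26 for integrated stress, -0.24 for cholesterol, -0.25 for glycolysis and hypoxia, 0.43 for mitochondrial transcripts, -0.56 for interferon and -0.79 for MHC class II genes.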

How the results depend on the processing

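The exon length correction and the fits of protein-coding genes alone were chosen only after the results were seen, and the cause of the shifts below was not tested except where fewer genes or libraries explain it. Among named genes, leaving out a library kept call and direction in 1135 instances, ended a call in 150 and made one in 8, and other settings did so in 1605, 94 and 38, with no reversal. For gene lists it kept them in 604, ended a call in 60 and reversed 2, and other settings did so in 380, 173 and 2.

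Without a filter on low counts 1655 genes passed for mutant against wild type in total RNA, 527 for translational efficiency and 823 for the line difference in HHT response. With DESeq2 these were 1084 for the mutant in total RNA, 328 in RiboLace and 468 for translational efficiency, and limma-voom called 75 for translational efficiency. With an absolute log2 fold change of at least 1, 4338 genes passed for HHT, 222 for the mutant and 883 in RiboLace. Leaving out 1 library gave 43 to 649 genes for the mutant in total RNA, 247 to 1956 in RiboLace, 24 to 1498 for translational efficiency, 178 to 1089 for the line difference, 10482 to 10787 for HHT, 5741 to 7314 for RiboLace against total RNA in wild type and 4720 to 7885 in mutant F3; where a group keeps 1 library, that library is assumed to vary like the others. For the mutant in total RNA, line means gave 2846 genes, F3 alone 3080, G7 alone 2059 and all total RNA libraries 903. All 14 libraries in 1 fit gave 1963 for RiboLace, and F3 and G7 total RNA together gave 11 for translational efficiency. Protein-coding genes alone gave 361 for translational efficiency, and removal of the length trend 738 for RiboLace.

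With library totals alone, the median of all genes moved by 0.23 for HHT, where 6684 rises (61.9%, against 50.4% in the TMM fit) stood against 4115 falls. For translational efficiency they gave 151 genes with 47.7% up, against 32.3% with TMM, and for RiboLace against total RNA in wild type a median of all genes of -0.14; DESeq2 gave 0.11 for mutant F3. Of 224 list tests 93 passed, 97 with library totals, 68 with fry and 0 with camera's estimated correlation (17 at an unadjusted p under 0.05).

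With the replicate numbers of the titles as a block, 2641 genes passed for the mutant in total RNA, where G7 has no wild-type partner and is left out as in F3 alone (3080), 2153 for the line difference, 1643 in RiboLace, 261 for translational efficiency and 10841 for HHT. With the numbers of the descriptions as a block the mutant comparison gave 0 genes in edgeR (1342 at an unadjusted p under 0.05), where the fit without the block gave 636 and DESeq2 1084, and HHT gave 10174. In that mutant comparison, description number 1 marks only wild-type replicate 1 and number 3 only mutant libraries. The genotype contrast then rests on number 2, with wild-type replicate 2 and mutant replicates 1 and 3. The count of 0 therefore cannot tell a shared replicate effect from the loss of libraries. Of HHT results the title block changed only the erythroid list (lost) and RUNX1, MCL1, CEBPA and CDK6 in the line difference (gained). The description block, not run for the line difference, changed none in HHT against control. Across the mutant and wild-type libraries the same title number meant no shared deviation (r of -0.046 in total RNA and -0.06 in RiboLace), so there the libraries share only a number; 4 of 4 controls and 3 of 4 HHT libraries correlated best with their own number. The median of ribosomal protein genes in the mutant turned from -0.07 to 0.000534 without wild-type replicate 1 (-0.134 without replicate 2), 0.02 with F3 alone and 0.0189 in those same libraries with the title block, and that of mitotic genes in the line difference from -0.14 to 0.00929 without control replicate 4 (-0.219 without replicate 3). The correlation of HHT and mutant effects was -0.0601, -0.104, -0.0568 and -0.0805 in the split controls, and that of mutant effects in total RNA and RiboLace 0.43 with F3 alone.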

Other observations

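No test in this part was chosen after its result was seen.

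The other lists add detail on HHT and the mutation. With HHT, ribosome biogenesis genes had a median of 0.30 with 39 of 68 up and 19 down (39 and 19 when adjusted over the list alone; camera adjusted p = 0.0591), NOP2, a ribosomal RNA methyltransferase, at 1.53 ± 0.06. The BCL2 family had a median of 0.26 with 7 of 14 up and 4 down (7 and 4 when adjusted over the list alone; adjusted p = 0.25). MYC-regulated genes went both ways, 28 of 59 up and 25 down (28 and 25 when adjusted over the list alone), with a median of 0.11 and a mean of -0.15 (adjusted p = 0.99), LDHA, lactate dehydrogenase, at -2.29 ± 0.07. Of the RUNX family and CBFB, 3 of 4 rose and 1 fell (3 and 1 when adjusted over the list alone; median 0.71, adjusted p = 0.256), CBFB, the RUNX partner, by 0.83 ± 0.07.

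Further lists moved little as a whole with HHT while many of their members changed. Translation factors had a median of -0.22 with 15 of 48 up and 28 down (15 and 28 when adjusted over the list alone; adjusted p = 0.106), EIF5 at 1.70 ± 0.07 and EIF4EBP1, a repressor of cap-dependent initiation, at -1.99 ± 0.07. Heat shock genes had a median of -0.33 with 7 of 25 up and 15 down (7 and 15 when adjusted over the list alone; adjusted p = 0.161), HSPA1B at -4.25 ± 0.21 and the collagen chaperone SERPINH1 at -2.59 ± 0.07. Haematopoietic transcription factors had 16 of 35 up and 13 down (17 and 13 when adjusted over the list alone; median 0.15, adjusted p = 0.648), IRF8, a factor of monocyte development, at -3.44 ± 0.06. Proteasome genes had 18 of 36 up and 5 down (18 and 5 when adjusted over the list alone; median 0.16, adjusted p = 0.165). Mitotic genes had 21 of 59 up and 22 down (21 and 22 when adjusted over the list alone; median -0.05, adjusted p = 0.798), and mitochondrial ribosomal protein genes 29 of 77 up and 24 down (28 and 24 when adjusted over the list alone; median 0.02, adjusted p = 0.895). Nuclear noncoding RNAs had 3 of 8 up and 2 down (3 and 2 when adjusted over the list alone; median -0.01, adjusted p = 0.711).

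In mutant total RNA several lists passed camera with small medians and few called members. MYC-regulated genes had a median of -0.12 (adjusted p = 0.00123, and adjusted p = 0.626 with an estimated correlation) with 1 of 60 down (3 when adjusted over the list alone). Ribosome biogenesis genes had a median of -0.11 (adjusted p = 0.00665, and adjusted p = 0.765 with an estimated correlation) with 0 of 68 called, also when adjusted over the list alone, a call lost without control replicate 1 (adjusted p = 0.074). With G7 alone the calls of MYC-regulated (adjusted p = 0.239), ribosome biogenesis (0.635), p53 target (0.0913) and heat shock genes (0.494) were lost, and with F3 alone that of glycolysis and hypoxia genes (0.732). Targets of p53 had a median of 0.20 (adjusted p = 0.0362, and adjusted p = 0.528 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.0737) or 2 (0.0839). Glycolysis and hypoxia genes had a median of -0.13 (adjusted p = 0.018, and adjusted p = 0.765 with an estimated correlation), lost without wild-type replicate 2 (0.24) or control replicate 3 (0.226). Heat shock genes had a median of -0.16 (adjusted p = 0.0473, and adjusted p = 0.765 with an estimated correlation), lost without wild-type replicate 2 (0.359) or control replicate 1 (0.218), 2 (0.0578) or 3 (0.118).

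Markers of other blood lineages were few in these cells. At least 10 reads were found in wild-type total RNA replicate 1 for 33 of 46 myeloid markers, 3 of 20 erythroid, 6 of 16 megakaryocyte, 8 of 22 lymphoid and 2 of 18 adherent cell markers. With HHT all 3 erythroid markers tested fell (3 when adjusted over the list alone; median -1.48, adjusted p = 0.0429, and adjusted p = 0.261 with an estimated correlation), TFRC, the transferrin receptor, at -3.02 ± 0.15, a list call lost without control replicate 3 (adjusted p = 0.0522) or with the replicate numbers as a block (0.0562). Medians were -0.88 for megakaryocyte (adjusted p = 0.256), -0.75 for lymphoid (adjusted p = 0.256) and -0.24 for adherent markers (adjusted p = 0.573), with 1 of 5, 2 of 7 and 1 of 4 up and 4, 5 and 2 down, as when adjusted over the list alone.

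TBC1D30 had 8510 and 10754 reads in wild-type total RNA, 10294 and 10152 in F3 controls and 5076 and 6260 in G7 controls. After HHT it had 51 and 44 reads in F3 and 22 and 28 in G7. In RiboLace it had 12 and 10 reads in wild type and 2 and 5 in the mutant.

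RUNX2 had 1013 and 1493 reads in wild-type total RNA but 9637 and 4089 in the shallower wild-type RiboLace libraries and 4522 and 2731 in mutant RiboLace. In wild-type RiboLace the RUNX partner CBFB had 155 and 106 reads and the paralog RUNX3 92 and 77.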
